A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

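Total RNA of the wild-type Saccharomyces cerevisiae strain CDY59 was hybridised to 2-colour yeast slides. RNA of cells kept in rich medium with 200 mM hydroxyurea for 1, 2, 4 or 6 h shared each slide with RNA of the untreated culture at an optical density of 0.5. Each time had 2 slides, with the treated RNA in channel 1 on the first and in channel 2 on the other. Each slide had 2 readings, titled with the French words faible and fort (weak and strong), whose meaning the labels do not give. The 16 readings therefore came from 8 slides. The labels do not say whether the 2 slides of a time held separate cultures or extracts, or whether all slides shared the same untreated RNA. The p-values thus measure how the difference between the 2 slides of a time varies from time to time, part or all of which may be technical. Spread of the response between times does not enter the error. Spread between cultures does not either, unless the 2 slides of a time held separate ones.

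Per the labels, RNA was extracted with a column kit and labelled indirectly. The deposited values were log ratios of the 2 channels of a reading, and their base was taken as log2. The base is not stated, a base of 10 would exceed the range of a 16-bit scanner at the largest absolute value of 6.16, and a natural logarithm could not be excluded. If the logarithm is natural, every log2 value printed here is the natural log ratio and the folds are larger. The table held 6912 spots with 2 decimals and no missing value. Reading medians ran from -1.03 to 0.45, so no centring by the authors was visible. Channel intensities were not used here, so no intensity-dependent correction was made, and signal over background is unknown. The precision is limited by the number of slides.

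The deposited ratios ran channel over channel, since slides of opposite orientation correlated below 0 at 4 h and 6 h before they were turned. All slides were turned to treated over untreated. The labels name no numerator, so the overall sign was set to make RNR2 and RNR4 positive, textbook hydroxyurea-induced genes. These were the 2 measured genes of 4 fixed for this purpose. The direction is therefore likely and not established, and these 2 genes are no independent evidence of it.

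Of the 6912 spots, 3344 named a single gene, 387 named several and 3181 named none. Spots with a single gene name gave 3127 genes, of which 207 had more than 1 spot and were averaged. The symbols of 3343 of these spots were matched through their gene number to a reference annotation, and 1 was not matched. No genome positions are given, since the build behind the slide is not known.

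Each reading was centred on the median of its single-gene spots, and the 2 readings of a slide were averaged, since they are not replicates. In the plan, centring stood as an alternative to the values as deposited. The uncentred medians led to these 2 being exchanged before any test was run, so values as deposited are an alternative added after the data were seen. A value of 0 is thus the median gene of each reading. As deposited, the median gene stood at 0.21 at 1 h, -0.215 at 2 h, 0.46 at 4 h and 0.29 at 6 h. It stood at 0.20 in the mean over the 4 times, 0.36 in the difference of 4 to 6 h from 1 to 2 h, and 0.11 in the difference of 6 h from 1 h. All changes are relative to the median gene. On values as deposited limma estimated infinite prior degrees of freedom, so every gene had the same variance there, and the counts as deposited differ from the others in this too.

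The linear model of limma 3.58.1 in R 4.3.3 had a coefficient for each of the 4 times and 1 for the channel orientation, which left 3 residual degrees of freedom per gene. Variances were moderated across genes with 4.89 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the 3127 genes and a threshold of 0.05. The comparisons were each time against 0, the mean of the 4 times against 0, the mean of 4 and 6 h minus that of 1 and 2 h, 6 h minus 1 h, and an F-test of any difference among the 4 times. Errors written with ± are standard errors of this model on the log2 scale. Treated and untreated RNA were compared within each slide. Slides of different times were not paired, because the times share no replicate numbers in the labels.

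A total of 23 gene lists were fixed with the comparisons, the thresholds and the rule for named genes before the data were examined. Of these, 22 had at least 3 measured genes. They were DNA damage and repair, iron uptake, iron-dependent enzymes, Yap1 oxidative stress, general stress, ribosomal proteins, ribosome biogenesis, histones, G1/S, G2/M and M/G1 transcripts, cell wall integrity, proteasome, heat shock chaperones, phosphate starvation, glucose-repressed metabolism, hexose uptake and glycolysis, ergosterol, amino acid synthesis, sulfur amino acids, mating, and meiosis and sporulation. The last 2 stand for other cell types or states. No gene of the 383 listed was in more than 1 list. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 22 lists. The same test with the correlation estimated for each list, and fry, were alternatives. Fry tests whether a list's genes moved on balance in 1 direction and does not compare them with other genes.

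Genes were named by rule: for the mean, the 12 largest changes in each direction, and for each time and for 4 to 6 h against 1 to 2 h, the 6 largest in each direction. They had to pass the test with the same sign on every slide of the comparison, or, for the last, with no overlap between the 2 sets of slides. The 4 members of each list with the largest absolute mean and the direction genes were also named. Any other gene was chosen after its values were seen.

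The alternatives tried were faible or fort readings alone, no orientation term, 2 other scalings, each spot on its own, robust variances, duplicateCorrelation over the 16 readings, and removal of readings differing by more than 1 log2 unit. A minimum absolute log2 ratio of 1, each slide or time left out, averaging of each time's slides, and the other list tests were also planned. Those added after the data were seen were values as deposited, centring in each of 48 blocks of spots, separate orientation terms for 1 to 2 h and 4 to 6 h, all spots, leaving out the 2 h slides in the comparison over time, and leaving out the 1 h and 2 h slides together in the mean.

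The model was tested on simulated data of 3127 genes. At a log2 change of 0.5, 1 and 2, it recovered 72%, 94% and 100% of 50 changed genes in the mean, and 12%, 58% and 92% at 6 h. For 4 to 6 h against 1 to 2 h it recovered 0%, 23.5% and 87.5% of 17, 17 and 16 genes. In the mean, 4.64% of its calls were false. Camera called 1 of 1 shifted list and 0 of 20 unshifted lists there. The simulated noise was independent between genes, so this says nothing of false list calls where the genes of a list vary together. It was also independent between slides, around an orientation effect common to all slides, as the model assumes. The recovery and the share of false calls may therefore differ in the real data.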

Results

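The slides compared RNA of hydroxyurea-treated CDY59 cells, at 1, 2, 4 and 6 h of treatment, with RNA of the untreated culture in which treatment began. Hydroxyurea inhibits ribonucleotide reductase and slows DNA replication. Each of the 4 times had 2 slides of opposite channel orientation, and each slide 2 readings of 6912 spots. A total of 3127 genes were tested. The median standard error was 0.0900 for the mean over the 4 times and 0.180 for a single time. The labels describe no untreated culture matched in time, so each ratio also holds any effect of further time in culture.

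The slides of a time, turned to treated over untreated, correlated across genes at -0.0809 at 1 h, -0.0339 at 2 h, 0.504 at 4 h and 0.579 at 6 h. Slides of different times correlated at a median of 0.564 over 12 pairs with the same orientation and 0.127 over 12 pairs with opposite orientation. Genes are not independent replicates, so these values carry no test. In the limma model, 540 genes passed for the effect of the channel orientation itself.

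The mean over the 4 times addresses the average response to hydroxyurea over the series, and its error holds no spread between times. RNR4 (YGR180C), a small subunit of ribonucleotide reductase, was higher by 2.55 ± 0.25 on the log2 scale (adjusted p = 0.000521, higher on 8 of 8 slides), a 5.87-fold ratio if the base is 2. RNR2 (YJL026W), the other small subunit, was higher by 2.69 ± 0.34 (adjusted p = 0.00157) on 7 of 8 slides. It stood at -0.98 on the 1 h slide with treated RNA in channel 1. These 2 genes set the direction and are not evidence of it.

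The other genes named by size that rose in the mean did so on 8 of 8 slides each, which the rule for naming required. AQY3 (YFL054C), of the aquaglyceroporin family, rose by 1.97 ± 0.10 (adjusted p = 5.42e-05) and HSP26 (YBR072W), a small heat shock chaperone, by 2.15 ± 0.15 (adjusted p = 0.000168). The peroxiredoxin genes AHP1 (YLR109W) and PRX1 (YBL064C) rose by 1.85 ± 0.11 (adjusted p = 0.000132) and 1.61 ± 0.10 (adjusted p = 0.000168). FIT3 (YOR383C), a cell wall protein that retains siderophore iron, rose by 1.73 ± 0.12 (adjusted p = 0.000168). YMR315W, SOR2 (YDL246C), YGP1 (YNL160W), APE1 (YKL103C), YNL134C and PSK2 (YOL045W) rose by 2.35, 1.71, 1.66, 1.64, 1.29 and 1.28, with adjusted p from 0.000168 to 0.000804.

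The genes named by size that fell in the mean did so on 8 of 8 slides each, which the rule for naming also required. EGT2 (YNL327W), DSE4 (YNR067C) and the chitinase gene CTS1 (YLR286C), which act in cell separation, had log2 ratios of -2.28 ± 0.15 (adjusted p = 0.000168), -1.93 ± 0.09 (adjusted p = 5.42e-05) and -1.60 ± 0.18 (adjusted p = 0.000911). The histone genes HTB2 (YBL002W) and HTA2 (YBL003C) had -1.66 ± 0.08 (adjusted p = 5.42e-05) and -1.28 ± 0.12 (adjusted p = 0.000361). The drug efflux pump gene PDR5 (YOR153W) had -1.52 ± 0.14 (adjusted p = 0.000361). AMN1 (YBR158W), an inhibitor of mitotic exit, had -1.45 ± 0.15 (adjusted p = 0.000585). The ribosomal protein genes RPS7B (YNL096C) and RPS21A (YKR057W) had -1.33 ± 0.09 (adjusted p = 0.000173) and -1.32 ± 0.10 (adjusted p = 0.000193). RPS3 (YNL178W), RPS7A (YOR096W) and RPS29B (YDL061C) had -1.87 ± 0.40 (adjusted p = 0.0152), -1.49 ± 0.43 (adjusted p = 0.0471) and -1.35 ± 0.30 (adjusted p = 0.0192). These last 3 rest in size on the 2 h slide with treated RNA in channel 1, where they stood at -5.36, -5.29 and -3.94. Without it they were -1.25 (adjusted p = 0.000446), -0.81 (adjusted p = 0.00159) and -0.87 (adjusted p = 0.000622). RPS3, RPS7A and RPS29B lost the call in 3, 11 and 5 of 25 alternatives, with adjusted p of up to 0.0716, 0.182 and 0.0880. All 3 lost it without the 6 h slide with treated RNA in channel 2 and without the 1 h slide with it in channel 2, RPS3 and RPS7A without the other 1 h slide, RPS7A and RPS29B without the 4 h slide with it in channel 2, and RPS7A without the other 6 h slide.

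In total 587 of 3127 genes passed in the mean by limma, 218 higher and 369 lower, and 233 of them had the same sign on all 8 slides. Of the 587, 70 had an absolute log2 ratio of at least 1. On values as deposited, whose median gene was 0.20, the count was 1042, with 816 higher and 226 lower. With the slides of each time averaged to 1 value it was 311, with 99 higher and 212 lower, and 288 of these were among the 587. The count was 255 with no orientation term, 293 without the 1 h slide with treated RNA in channel 1, 344 and 241 without the 4 h and the 6 h slide with it in channel 2, and 1417 on the 4 h and 6 h slides alone. That last fit left 1 residual degree of freedom per gene, against 5.92 prior ones, so its variances rested mostly on the prior.

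**Figure D1:**
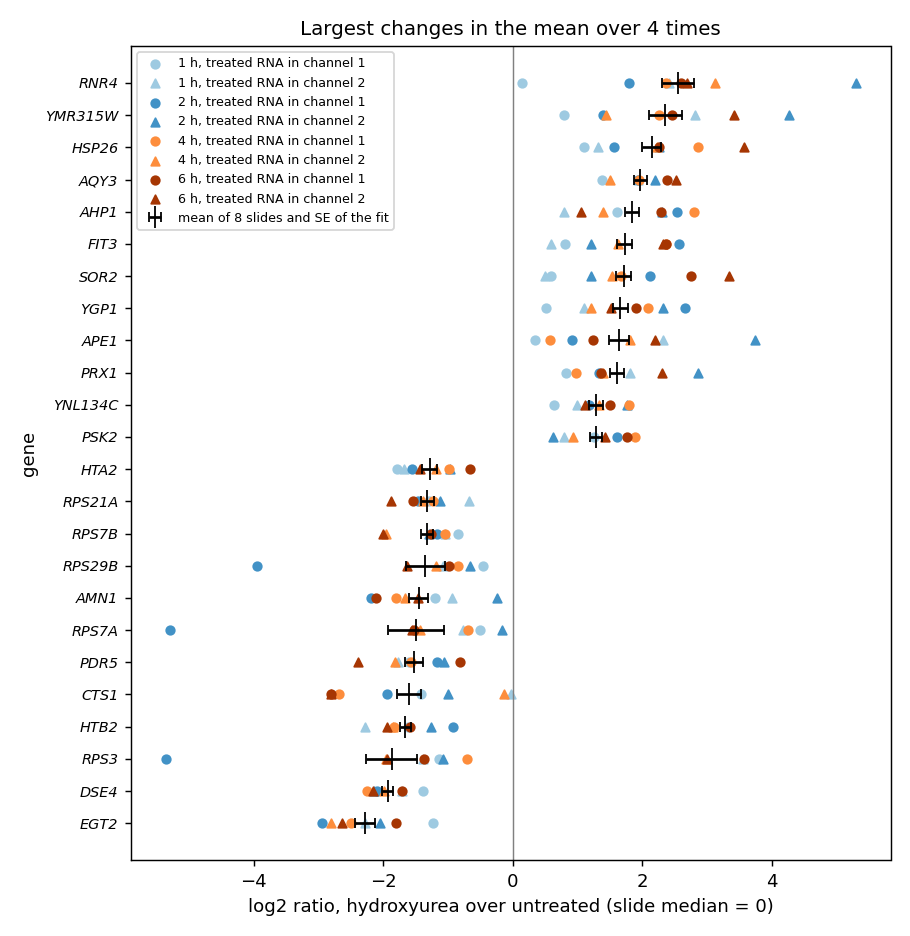
Log2 ratio of hydroxyurea-treated over untreated RNA (x axis, slide median set to 0) of the 24 genes with the largest changes in the mean over the 4 times (y axis), 12 in each direction, among those that passed with 1 sign on all 8 slides, which leaves out RNR2. Circles and triangles are the 8 slides, coloured by time and shaped by the channel of the treated RNA, and the black bars are the mean and its standard error in limma, from 2.55 for RNR4 to -2.28 for EGT2.

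Among the lists fixed beforehand, 4 were higher in the mean. General stress genes, the set induced by many stresses, had 16 of 18 measured members higher over all genes tested and 17 adjusted over the list alone, with a median of 0.71, above 0 on 8 of 8 slides. HSP26, YGP1, PGM2 (1.05 ± 0.13) and SOL4 (1.03 ± 0.10) led it, and camera gave an adjusted p = 1.21e-11, against an adjusted p = 0.189 with an estimated correlation. The Yap1 oxidative stress list had 14 of 21 members higher over all genes and 17 adjusted over the list alone, with a median of 0.37, above 0 on 8 of 8 slides. AHP1, the thioredoxin gene TRX2 (0.85 ± 0.08), the glutathione transferase gene GTT2 (0.78 ± 0.10) and AAD14 (0.75 ± 0.08) led it (camera adjusted p = 8.03e-10, adjusted p = 0.189 with an estimated correlation).

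Iron uptake genes had 5 of 17 members higher over all genes and 6 adjusted over the list alone, with a median of 0.20, above 0 on 7 of 8 slides, and all 17 means above 0. FIT3, the vacuolar metal transporter gene SMF3 (0.94 ± 0.12), the siderophore transporter gene ENB1 (0.73 ± 0.11) and COT1 (0.38 ± 0.10), a vacuolar transporter of zinc and cobalt, passed (camera adjusted p = 1.76e-05, adjusted p = 0.249 with an estimated correlation). COT1 lost the call in 12 of 25 alternatives (adjusted p up to 0.164). On values as deposited the median gene stood at 0.20, so the direction of a list above 0 could not turn there. Glucose-repressed genes had 3 of 13 members higher over all genes and 4 adjusted over the list alone, with a median of 0.16, above 0 on 8 of 8 slides. ALD4 (0.48 ± 0.09), FOX2 (0.38 ± 0.09) and MAL32 (0.37 ± 0.09) passed, and CIT2 was at 0.48 (adjusted p = 0.0905). ALD4, FOX2 and MAL32 lost the call in 7, 8 and 11 of 25 alternatives. The camera adjusted p was 0.00352, against an adjusted p = 0.199 with an estimated correlation.

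Growth and cell cycle lists made up the 6 that were lower. Cytosolic ribosomal protein genes had 45 of 49 measured members lower over all genes and 47 adjusted over the list alone, with a median of -0.98, below 0 on 8 of 8 slides (camera adjusted p = 5.11e-26, adjusted p = 0.199 with an estimated correlation). Ribosome biogenesis genes had 18 of 39 lower over all genes and 26 adjusted over the list alone, with a median of -0.44, below 0 on 7 of 8 slides. GAR1 (-1.04 ± 0.09), MAK21 (-0.99 ± 0.09), NOP15 (-0.97 ± 0.09) and NOP58 (-0.97 ± 0.11) led it (camera adjusted p = 2.26e-10, adjusted p = 0.219 with an estimated correlation). The Gcn4 amino acid synthesis list had 5 of 15 lower, over all genes and adjusted over the list alone, with a median of -0.19, below 0 on 6 of 8 slides. HOM2 (-0.67 ± 0.13), BAT1 (-0.62 ± 0.14) and LEU4 (-0.58 ± 0.14) passed, and ILV2 was at -0.58 (adjusted p = 0.124). HOM2, BAT1 and LEU4 lost the call in 3, 9 and 9 of 25 alternatives. The list's camera adjusted p was 0.0463, against an adjusted p = 0.751 with an estimated correlation. The list lost the call in 9 of 24 alternatives, among them without the 2 h slide with treated RNA in channel 1 (adjusted p = 0.282) and with fry (adjusted p = 0.466), in a range of adjusted p from 0.000364 to 0.751.

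M/G1 transcripts, expressed as cells leave mitosis, had 12 of 16 lower over all genes and 14 adjusted over the list alone, with a median of -0.67, below 0 on 8 of 8 slides. EGT2, DSE4, CTS1 and AMN1 led it (camera adjusted p = 1.64e-09, adjusted p = 0.189 with an estimated correlation). G2/M transcripts had 4 of 10 lower over all genes and 9 adjusted over the list alone, with a median of -0.34, below 0 on 8 of 8 slides. The mitotic cyclin gene CLB1 (-0.86 ± 0.14), ALK1 (-0.68 ± 0.11) and IRC8 (-0.39 ± 0.10) passed, and HST3 was at -0.49 (adjusted p = 0.0683). IRC8 lost the call in 17 of 25 alternatives (adjusted p up to 0.249) and ALK1 in 1. The camera adjusted p was 0.000723, against an adjusted p = 0.189 with an estimated correlation. Histone genes had 3 of 4 measured members lower over all genes and 4 adjusted over the list alone, with a median of -1.05, below 0 on 8 of 8 slides. HTB1 had -0.81 ± 0.09, and the variant histone gene HTZ1 -0.30 (adjusted p = 0.0592). The camera adjusted p was 0.000107, against an adjusted p = 0.189 with an estimated correlation.

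Over the 22 lists, 10 passed by camera with the preset correlation, 11 by fry and 0 by camera with an estimated correlation, where 5 had an unadjusted p under 0.05.

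The other 12 lists did not pass in the mean. DNA damage and repair genes had 1 of 17 higher, over all genes and adjusted over the list alone: the checkpoint kinase gene DUN1 (0.92 ± 0.14, adjusted p = 0.00343, 8 of 8 slides). MAG1, RAD54 and RAD5 were at 0.46, 0.31 and 0.24, and the list's camera adjusted p was 0.0504. It gained the call in 12 of 24 alternatives, with adjusted p from 0.0130 to 0.404 and of 0.0235 by fry. Sulfur amino acid genes had the same list p (8 of 24 alternatives gained the call, adjusted p from 0.0290 to 0.427, 0.0374 by fry), with STR3 (0.36) and MET14 (0.28) higher of 15 over all genes and 0 adjusted over the list alone by limma, with 3 at an unadjusted p under 0.05. STR3 and MET14 lost the call in 12 and 15 of 25 alternatives (adjusted p up to 0.216 and 0.293). Cell wall integrity genes had PRM5 (0.46) and YPS1 (0.40) higher and PST1 (-1.05) lower of 11 (list adjusted p = 0.332), with 2 and 1 also adjusted over the list alone. Proteasome genes had PRE5 (0.48) and RPN4 (0.42), the regulator of the set, higher and RPN8 (-0.63) lower of 23 (list adjusted p = 0.497), with 2 and 1 also adjusted over the list alone. G1/S transcripts had RFA2 (0.43) higher and the G1 cyclin genes CLN2 (-0.48) and CLN1 (-0.35) lower of 26 (list adjusted p = 0.604), with 1 and 2 also adjusted over the list alone. Of 25 alternatives, PRM5 and YPS1 lost the call in 11 each, RPN8 and CLN1 in 10 each, PRE5 and RFA2 in 6 each and CLN2 in 5.

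Iron-dependent enzyme genes had 2 higher and 4 lower of 23 over all genes, and 3 higher and 5 lower adjusted over the list alone (list adjusted p = 0.885). Among them were the glutamate synthase gene GLT1 (-0.84 ± 0.12) and RIP1 (-0.51 ± 0.14) of the respiratory chain, and ILV3 was at -0.94 (adjusted p = 0.0505). Mating genes, a mark of haploid cells, had FAR1 (-0.88 ± 0.18) and AGA1 (-0.59 ± 0.11) lower of 14, the same count of 2 adjusted over the list alone, and a list adjusted p of 0.95. Their median of 0.12 and their mean of -0.09 differed in sign, and the test pointed down. The phosphate starvation list had VTC4 (-0.53) lower of 6, with 1 higher and 2 lower adjusted over the list alone (list adjusted p = 0.949). Its median was 0.06 and its mean -0.08, and its test pointed up. Glycolysis genes had PFK1 (-0.38 ± 0.08) lower of 15, the same count of 1 adjusted over the list alone (list adjusted p = 0.872). Ergosterol genes had CYB5 (-0.36) lower of 12 over all genes and 0 adjusted over the list alone by limma, with 4 at an unadjusted p under 0.05 (list adjusted p = 0.31). The 13 heat shock chaperone genes and the 6 meiosis and sporulation genes had 0 passing by limma in either count, with 3 each at an unadjusted p under 0.05 and list adjusted p of 0.31 and 0.134. The meiosis and sporulation median of 0.20, above 0 on 5 of 8 slides, was close to that of the iron uptake list and above the 0.16 of the glucose-repressed list. Of 25 alternatives, RIP1 and CYB5 lost the call in 12 each, PFK1 in 9, VTC4 in 8, FAR1 in 3, and GLT1 and AGA1 in 2 each.

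**Figure D2:**
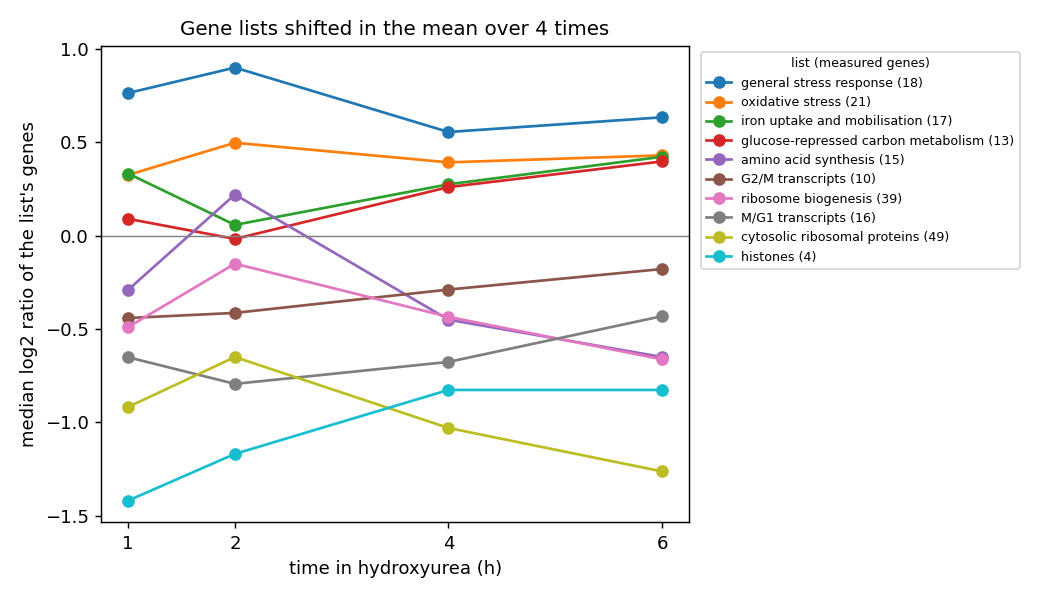
Median log2 ratio of hydroxyurea-treated over untreated RNA (y axis) of the measured genes of each of the 10 lists that passed in the mean, against hours in hydroxyurea (x axis), with a line per list. Ribosomal protein genes went from -0.92 at 1 h to -1.26 at 6 h, and general stress genes stood between 0.56 and 0.90.

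At 1 h, the comparison addresses the earliest response sampled. The histone genes HTB2 and HTA2 were lower, at -1.95 ± 0.17 (adjusted p = 0.00963) and -1.74 ± 0.23 (adjusted p = 0.0319). PDR5, DSE4, RPL4A and RPS15, the last 2 coding for ribosomal proteins, had -1.68, -1.55, -1.39 and -1.38. AQY3 rose by 1.66 ± 0.20 and TRX2 by 1.39 ± 0.17 (both with an adjusted p = 0.0302), and STF2, PRX1, YOR289W and RTC3 rose by 1.34, 1.32, 1.21 and 1.21. These 12 genes lost the call in 3 to 7 of 18 or 19 alternatives each. The camera test passed for 11 lists. General stress, Yap1, iron uptake, DNA damage, sulfur and proteasome genes were higher, and ribosomal protein, ribosome biogenesis, histone, G2/M and M/G1 genes lower. The proteasome slide medians were -0.09 and 0.47, so that call rests on 1 orientation. The p of the 11 lists with an estimated correlation ran from an adjusted p = 0.225 to an adjusted p = 0.652, and 1 list passed by fry. In all 25 genes passed by limma, 8 higher and 17 lower (46 and 40 as deposited), against 379 at an unadjusted p under 0.05. Without either 1 h slide 0 passed by limma, and with no orientation term 0 passed, while without either 2 h slide 86 did and without either 6 h slide 4 did.

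At 2 h, the ribonucleotide reductase genes RNR4 and RNR2 were higher by 3.55 ± 0.50 (adjusted p = 0.0111) and 3.23 ± 0.67 (adjusted p = 0.0411). YMR315W, YGP1, AHP1 and the flavohemoglobin gene YHB1 rose by 2.83, 2.50, 2.42 and 2.37. EGT2 and DSE4 were lower at -2.50 ± 0.31 (adjusted p = 0.00783) and -2.12 ± 0.17 (adjusted p = 0.00325). The translation initiation factor gene SUI1, SFG1, the RNA polymerase I subunit gene RPA49 and the ribosome assembly gene MRT4 had -1.73, -1.61, -1.52 and -1.40. YHB1, SUI1 and RPA49 lost the call in 8 of 19 alternatives each, within 1.00 to 3.73, -2.57 to -0.89 and -2.19 to -0.86, and with adjusted p up to 0.424, 0.277 and 0.3. YMR315W lost it in 7 of 19 (1.75 to 3.90), SFG1 in 4 (-2.17 to -1.06), MRT4 in 3 and EGT2 in 1, and RNR2, RNR4 (2.32 to 4.78) and AHP1 in 7, 2 and 1 of 18. The camera test passed for 10 lists. General stress, Yap1, cell wall, proteasome and glycolysis genes were higher, and the 5 lower lists were those of 1 h by name. Their adjusted p with an estimated correlation ran from an adjusted p = 0.274 to an adjusted p = 0.575, and 4 lists passed by fry. The glycolysis median of 0.68 came from slide medians of -0.24 and 1.48, and the slides also differed in sign for cell wall (-0.22 and 1.25), proteasome (-0.06 and 0.58) and ribosome biogenesis genes (-0.69 and 0.20). In all 131 genes passed, 104 higher and 27 lower (87 and 150 as deposited, 58 and 69 after quantile normalization). The count was 39 after scaling to the same median absolute value, 29 higher and 10 lower, and 74 with faible readings, 59 higher and 15 lower. Which direction prevailed depended on the slides: 39 higher and 90 lower passed without the 2 h slide with treated RNA in channel 2, and 118 and 3 without the other. With no orientation term 5 passed, and without either 1 h slide 82 did.

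At 4 h, RNR4 was higher by 2.75 ± 0.50 (adjusted p = 0.0274) and HSP26 by 2.54 ± 0.29 (adjusted p = 0.00954). AHP1, FIT3, AQY3 and YGP1 rose by 2.10, 1.99, 1.73 and 1.65. EGT2 and DSE4 were lower at -2.65 ± 0.31 (adjusted p = 0.00954) and -2.12 ± 0.17 (adjusted p = 0.00705). PSA1, which makes GDP-mannose for glycosylation, HTB2, GLT1 and AMN1 had -1.86, -1.84, -1.78 and -1.74. RNR4 lost the call in 7 of 18 alternatives and the other 11 genes in 1 to 4 of 18 or 19. The camera test passed for 14 lists. General stress, Yap1, iron uptake, DNA damage, glucose-repressed and meiosis genes were higher, and the 5 lower lists of 1 h were lower, with heat shock, glycolysis and amino acid synthesis genes. Their p with an estimated correlation ran from an adjusted p = 0.273 to an adjusted p = 0.625, and 0 lists passed by fry, where 9 had an unadjusted p under 0.05. In all 88 genes passed by limma, 19 higher and 69 lower, against 668 and 58 on values as deposited, whose median gene was at 0.46. Without the 4 h slide with treated RNA in channel 1 or channel 2, 0 and 6 (4 higher, 2 lower) passed by limma, against 530 at an unadjusted p under 0.05 on all slides, without either 2 h slide 233 did, and with no orientation term 1 did.

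At 6 h, the last time sampled, RNR2 and RNR4 were higher by 3.10 ± 0.67 (adjusted p = 0.0388) and 2.65 ± 0.50 (adjusted p = 0.022). SOR2 rose by 3.04 ± 0.24 and AQY3 by 2.45 ± 0.20 (both with an adjusted p = 0.00189), and YMR315W and HSP26 by 2.94 and 2.92. CTS1 was lower at -2.80 ± 0.36 (adjusted p = 0.00683) and PSA1 at -2.39 ± 0.19 (adjusted p = 0.00189). The alpha-agglutinin gene SAG1, EGT2, DSE4 and AMN1 had -2.45, -2.22, -1.93 and -1.78. RNR2 (1.70 to 4.49) and RNR4 (1.60 to 3.69) lost the call in 5 and 3 of 18 alternatives, and the other 10 genes in 1 to 4 of 18 or 19. Ribosomal protein genes had 27 of 49 lower over all genes and 42 adjusted over the list alone, with a median of -1.26. The camera test passed for 10 lists. General stress, Yap1, iron uptake, glucose-repressed and meiosis genes were higher, and ribosomal protein, ribosome biogenesis, histone, M/G1 and amino acid synthesis genes lower. Their p with an estimated correlation ran from an adjusted p = 0.309 to an adjusted p = 0.585, and 7 lists passed by fry. In all 188 genes passed by limma, 52 higher and 136 lower (256 and 106 as deposited). Without the 6 h slide with treated RNA in channel 1 or channel 2, 13 (9 higher, 4 lower) and 0 passed by limma, against 830 at an unadjusted p under 0.05 on all slides, without either 2 h slide 382 did, and with no orientation term 28 did.

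The mean of 4 and 6 h minus that of 1 and 2 h addresses whether the response changed with longer treatment. No single gene passed: the count by limma was 0, with 549 at an unadjusted p under 0.05, of which 150 were higher and 399 lower later. The smallest adjusted p was 0.0923. By list, camera passed 9. Proteasome genes, with 23 of 23 members below 0, had a median difference of -0.47 (adjusted p = 8.57e-05, adjusted p = 0.645 with an estimated correlation). Amino acid synthesis genes had -0.61 (adjusted p = 0.000921, adjusted p = 0.645 with an estimated correlation) and ribosomal protein genes -0.36 (adjusted p = 0.000921, adjusted p = 0.674 with an estimated correlation). Glycolysis genes had -0.60 (adjusted p = 0.00116, adjusted p = 0.645 with an estimated correlation), heat shock chaperone genes -0.52 (adjusted p = 0.0101, adjusted p = 0.666 with an estimated correlation) and G1/S transcripts -0.19 (adjusted p = 0.0288, adjusted p = 0.645 with an estimated correlation).

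Meiosis and sporulation genes had 0.40 (adjusted p = 0.000921), glucose-repressed genes 0.25 (adjusted p = 0.0158) and iron uptake genes 0.18 (adjusted p = 0.0228), each with an adjusted p = 0.645 with an estimated correlation. The meiosis and sporulation list, which stands for another cell state, thus rose the most, so a rise of this size was not particular to the other lists. By fry 0 lists passed, with 3 at an unadjusted p under 0.05. On values as deposited, whose median gene was 0.36 higher later, ribosomal protein genes had 0.03 and G1/S transcripts 0.20, so both turned sign, and the other 7 lists did not. Without the 2 h slides, glycolysis (-0.22, adjusted p = 0.247) and iron uptake (0.16, adjusted p = 0.0999) lost the call in the difference from 1 h, and the other 7 kept it, at adjusted p from 0.00514 to 0.0469. Glycolysis slide medians at 1 h were -1.11 and 0.49 by orientation, and those of glycolysis, heat shock, amino acid synthesis, proteasome and G1/S genes differed in sign between orientations at both 1 h and 2 h.

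By limma 137 genes passed without the 2 h slide with treated RNA in channel 1, 3 without the other 2 h slide, and 110 with separate orientation terms, against 0 with all slides and 0 between 4 to 6 h and 1 h without both. By duplicateCorrelation over readings 176 passed, 170 of them lower, and after quantile normalization 66 did, with 15 higher and 51 lower. As deposited 78 passed, with 67 higher and 11 lower.

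The difference of 6 h from 1 h gave 0 genes by limma, with 237 at an unadjusted p under 0.05 and a smallest adjusted p of 0.132. PSA1 was at -2.01 and SOR2 at 2.50 (both with an adjusted p = 0.132). The F-test of any difference among the 4 times gave 0 genes by limma, with 377 at an unadjusted p under 0.05. The smallest adjusted p was 0.0632, for RTN1, chosen after its values were seen, with log2 ratios of -0.89, 1.56, -0.61 and -0.94 at 1, 2, 4 and 6 h. By duplicateCorrelation 8 genes passed for 6 h against 1 h and 133 in the F-test. As deposited the counts were 20 and 86, and without the 2 h slide with treated RNA in channel 1 they were 4 and 58.

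**Figure D3:**
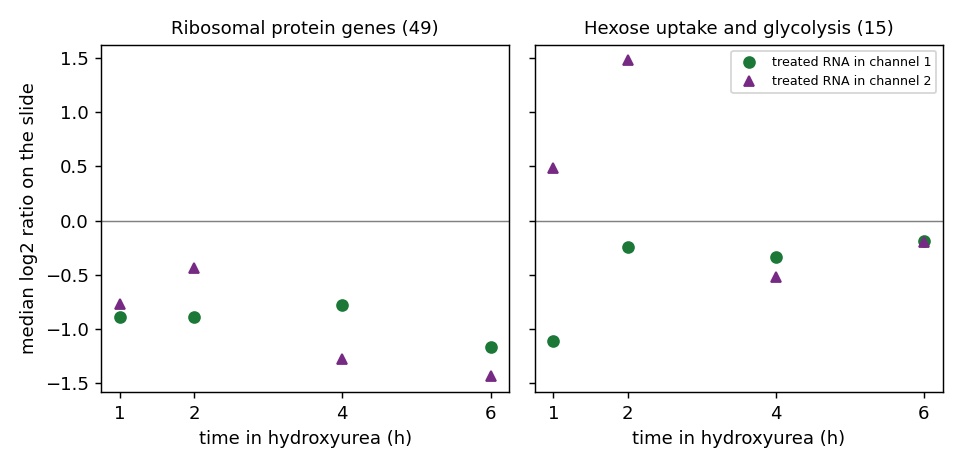
Median log2 ratio of treated over untreated RNA on each of the 8 slides (y axis) against hours in hydroxyurea (x axis), for the 49 ribosomal protein genes and the 15 hexose uptake and glycolysis genes, with shape and colour giving the channel of the treated RNA. Ribosomal protein medians lay between -1.44 and -0.44, and glycolysis medians between -1.11 and 1.48.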

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

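The tests of channel bias at 1 h and 2 h, of the 2 h slides alone, of signal compression and of growth stage were chosen only after the result was seen, as was the requirement that a value exceed 2 standard errors in the tests of the 2 h slides and of signal compression.

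Of 22 lists, 9 differed between 4 to 6 h and 1 to 2 h by a direct test of the difference (camera). The median differences on the log2 scale were -0.61 for amino acid synthesis, -0.60 for hexose uptake and glycolysis, -0.52 for heat shock chaperones, -0.47 for the proteasome, -0.36 for cytosolic ribosomal proteins and -0.19 for G1/S transcripts. They were 0.40 for meiosis and sporulation, 0.25 for glucose-repressed metabolism and 0.18 for iron uptake. With an estimated correlation all 9 lost the call, at adjusted p from 0.645 to 0.674.

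For these lists, 34 of the 35 splits of the 8 slides into 4 and 4 could be fitted with the orientation term, and the split by orientation could not. Of these, 6 gave 9 or more lists, the real one included with 9, and the highest other gave 11, so chance could not be excluded. In the 3 splits that keep the slides of each time together, the real one gave 9 lists and the highest other 5, but 3 splits are too few to decide. Without the 2 h slides, the 6 lower lists had a median difference of -0.242 from 1 h, and 6 of 6 were negative. A separate fit to the median of these lists on each slide gave a standard error of 0.392 for this comparison. That spread leaves it open whether the 2 h slides alone may account for the lower lists, and 7 of the 9 passed without them, all but glycolysis (-0.22, adjusted p = 0.247) and iron uptake (0.16, adjusted p = 0.0999). Longer treatment stays open as an untested biological explanation, as it cannot be separated from time in culture.

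For single genes in the same comparison, the count at an unadjusted p under 0.05 was 543 in a model with the 2 periods and orientation, reached by 1 of 34 splits, the real one, with 413 as the highest other. The bound set beforehand would exclude chance on this share, but it took the slides as separate cultures, and the labels do not say whether the 2 slides of a time shared a culture. Only 3 splits keep the slides of each time together, too few for a share under 0.05 (543 in the real one, 113 as the highest other), so chance could not be excluded. The count at adjusted p 0.05 was 0 by limma, which any split reaches, so that its 34 of 34 splits, with 1 as the highest other, say nothing about chance.

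The slides of a time correlated near 0 at 1 h and 2 h (-0.0809 and -0.0339) and at 0.504 and 0.579 at 4 h and 6 h. A weaker response at 1 h and 2 h could not be told from other causes. After removal of the orientation effect estimated from the other times, the covariance of the paired slides at 1 to 2 h was 0.354 times that at 4 to 6 h. This was below the 0.5 set beforehand, but it restates the low correlation. The counts of genes passing do not settle it. They were 25, 131, 88 and 188 at 1, 2, 4 and 6 h, and 65, 39, 234 and 309 after scaling to the same median absolute value. Whether a channel bias of single genes shared by all slides contributes stays open. With the bias estimated at 4 h and 6 h removed, the correlations became 0.0923 at 1 h and 0.155 at 2 h, between the bounds of 0.1 and 0.3 at 2 h, so this test did not decide. The reverse removal went the other way from what a shared bias predicts. With the bias estimated at 1 h and 2 h removed, the correlations fell to 0.294 at 4 h and 0.408 at 6 h. These values carry no estimate of spread. A bias that differs between slides was not tested as a cause of these correlations. With separate orientation terms for 1 to 2 h and 4 to 6 h, 114, 324, 286 and 505 genes passed by limma at the 4 times.

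Ribosomal protein transcripts were lower in treated cells, with 45 of 49 passing in the mean. A channel bias of abundant transcripts would turn the sign with the orientation, and the list's median was below 0 on 8 of 8 slides, which argues against it. Signal compression of abundant transcripts would draw their ratios as deposited toward 0 and not past it, if these ratios hold no offset from earlier processing. Whether they hold one is not known. The mean shift of the ribosomal protein list stayed between -1.08 and -0.75 in 24 alternatives, values as deposited included. Only the values as deposited bear on this, since the other alternatives were centred. If they hold no offset, they argue against compression as the sole cause, and otherwise they do not decide. A part in the centred value stays open, since the median gene as deposited stood at 0.20. Glycolysis genes did not decide on that part: their median of -0.09 was 0.0882 times the ribosomal protein median. Over the 8 slides, the glycolysis median minus a set fraction of the ribosomal protein median had a standard error of 0.256. That spread is too wide to tell. A later growth stage of the treated culture could not be told apart from the treatment. The 1 h median was 0.727 times the 6 h median, between the bounds of 0.33 and 0.8. The treatment itself stays open as the biological explanation.

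Spots without a single gene name, outside the comparisons of genes, also carried signal. In the mean over the 4 times 486 of 3568 passed by limma, 144 higher and 342 lower, between log2 ratios of 2.85 and -1.57. Of these, 402 had no gene name and 84 had several.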

How the results depend on the processing

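Values as deposited, centring in blocks, separate orientation terms, all spots, leaving out the 2 h slides in the comparison over time, and leaving out the 1 h and 2 h slides together were chosen only after the data were seen. The cause of each change below was not tested, except that fewer slides or readings, more spots, the 11 residual degrees of freedom from counting readings in duplicateCorrelation, and the single variance for all genes as deposited are part of those alternatives by construction. Signal over background is unknown. The 2 filters on missing values removed nothing and say nothing of stability. For lists, robust variances, duplicateCorrelation, single spots, all spots, a minimum log2 ratio and the average of each time's slides, which treats a time as 1 unit, were not run. A lone slide of a time is assumed to vary like the others.

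The 587 genes of the mean kept their sign in the alternatives compared gene by gene, except 1 gene without the 1 h and 2 h slides, and 9 were not tested after removal of differing readings. Tested as single spots, 624 of their 627 spots had the same sign, and 3 genes had a spot of the other sign. Most of the 587 genes had 1 spot, whose value is that of the gene, so only the genes with more spots bear on this. Of the 255 calls with no orientation term all were shared with the 587, as were 390 of 392 with faible readings and 429 of 1042 as deposited. The list count stayed within 9 to 15 of the 22, except with an estimated correlation.

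Counts more than 1.5 times away from those reported are given by alternative. With faible readings they were 5 at 1 h, 74 at 2 h, 42 at 4 h, 109 at 6 h and 1 in the F-test. With fort readings they were 47 at 1 h, 167 at 4 h, 290 at 6 h and 1 for 6 h minus 1 h. With no orientation term they were 0, 5, 1 and 28 at 1, 2, 4 and 6 h and 255 in the mean. Scaling to the same median absolute value gave 65, 39, 234 and 309 at the 4 times, 10 for late minus early and 1 for 6 h minus 1 h. Quantile normalization gave 163, 315 and 404 at 1, 4 and 6 h, 66 for late minus early, 3 for 6 h minus 1 h and 12 in the F-test. With duplicateCorrelation there were 110, 353, 286 and 449 at the 4 times, 890 in the mean, 176 for late minus early, 8 for 6 h minus 1 h and 133 in the F-test. As deposited there were 86, 237, 726 and 362 at the 4 times, 1042 in the mean, 78 for late minus early, 20 for 6 h minus 1 h and 86 in the F-test. With all spots there were 60, 242, 239 and 435 at the 4 times, 1115 in the mean and 8 for late minus early. Separate orientation terms gave 114, 324, 286 and 505 at the 4 times, 110 for late minus early, 2 for 6 h minus 1 h and 3 in the F-test. A minimum absolute log2 ratio of 1 gave 86 at 2 h, 118 at 6 h and 70 in the mean. The mean gave 936, 353 and 248 without the 2 h, 4 h or 6 h slides, 1417 without the 1 h and 2 h slides (1 residual degree of freedom per gene), and 311 with each time's slides averaged. Removal of differing readings gave 1 in the F-test, and camera with an estimated correlation gave 0 lists, with 5 at an unadjusted p under 0.05 and 11 by fry.

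With each slide left out in turn, the counts ranged from 0 to 86 at 1 h, 82 to 129 at 2 h, 0 to 233 at 4 h and 0 to 382 at 6 h. They ranged from 241 to 814 in the mean, 0 to 137 for late minus early, 0 to 4 for 6 h minus 1 h, 0 to 58 in the F-test and 9 to 12 for lists. The 2 h calls were 39 higher and 90 lower without the 2 h slide with treated RNA in channel 2, and 118 and 3 without the other, against 104 and 27.

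In the mean, values that turned sign belonged to lists and genes that had not passed. Of those that turned, only the proteasome list (-0.22, adjusted p = 0.0362) and MET17 (-0.58, adjusted p = 0.00286) then passed in the opposite direction, both without the 1 h and 2 h slides. Between 4 to 6 h and 1 to 2 h, ribosomal proteins (0.03) and G1/S transcripts (0.20), which had passed by camera with a lower value, turned sign as deposited. As deposited, the mean shift of iron-dependent enzymes and respiration was 0.11, of heat shock chaperones 0.045, of phosphate starvation 0.11, of hexose uptake and glycolysis 0.15, of ergosterol synthesis 0.077 and of mating pheromone response 0.10. Without the 1 h slides the shift of G1/S transcripts was -0.0084, of proteasome -0.013 and of hexose uptake and glycolysis 0.0057. Without the 2 h slides G1/S transcripts were at -0.042, cell wall integrity at -0.080 and proteasome at -0.10. Without both, G1/S transcripts were at -0.11, cell wall integrity at -0.0041, proteasome at -0.22 and phosphate starvation at 0.0027. Hexose uptake and glycolysis was at 0.059 without the 4 h slides, 0.046 without the 6 h slides and 0.049 with faible readings, and proteasome at -0.0011 with fort readings. With each slide left out in turn, the shift ranged from -0.013 to 0.044 for G1/S transcripts, -0.024 to 0.15 for cell wall integrity, -0.049 to 0.10 for proteasome, -0.20 to 0.11 for hexose uptake and glycolysis, -0.23 to 0.0024 for ergosterol synthesis, and -0.071 to 0.60 for SCW4. TDH3 was at -0.049 and MET17 at -0.14 without the 2 h slides, and TDH2 at -0.018 and MET17 at -0.58 without the 1 h and 2 h slides.

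Of the 24 genes named by size in the mean, RPS3, RPS7A and RPS29B lost the call in some alternatives and the other 21 kept it in the 24 or 25 alternatives run for each gene. Over named genes and their comparisons, 2759 of the values stayed on their side of the threshold, 406 lost the call and 201 gained it.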

Other observations

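The comparisons of these genes over time and of spots were chosen only after the result was seen.

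MET17, an enzyme of sulfur amino acid synthesis, was higher at 2 h by 1.43 ± 0.22 (limma adjusted p = 0.0142) and lower at 6 h at -1.05 ± 0.22 (adjusted p = 0.037). Its difference of 4 to 6 h from 1 to 2 h was -1.67 (adjusted p = 0.0923), so a change over time did not pass. TRX2 stood at 1.39, 0.93, 0.85 and 0.22 at 1, 2, 4 and 6 h, with a difference of -1.17 between 6 h and 1 h (adjusted p = 0.344).

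For the 197 genes with 2 spots, the means of the spots correlated at r = 0.592 across genes, with a median absolute difference of 0.127, and 4 genes differed by more than 1 on the log2 scale. Over the 8 slides, spots of the same gene correlated at a median of 0.0992 over 207 genes, against -0.00462 in 1000 random pairs of spots. The 2 spots of NOP58 were at -1.11 and -0.83 in the mean, and those of the pheromone receptor gene STE3 at -0.50 and -0.02.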
